A study of Mus musculus with 7 samples.

How the data were processed

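RNA of mouse spleen monocytes was profiled on 7 Affymetrix Mouse Gene 2.0 ST arrays, each hybridised with material from 1 mouse under 1 condition. Mouse 1 gave an unstimulated, an HL7G, an R848, a CpG B and a poly I:C sample, and mouse 2 gave an unstimulated and an HL7G sample. Per the labels, selected monocytes with wild-type EPCR were stimulated for 3 h, RNA was extracted with TRIzol and prepared with the WT PLUS kit. How the monocytes were selected and how long the unstimulated cells were kept in culture are not given in the sources used here. The protocol also names an IgG condition, which was not analysed here.

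The values are log2 expression levels per probe set, as the authors deposited them, with 1 column per array. The submitters' processing notes name RMA (background correction, quantile normalization and summary of probes into probe sets), Affymetrix Expression Console and Transcriptome Analysis Console, with no versions. The deposited table held 41345 probe sets. Array medians over all probe sets lay between 4.40 and 4.54. No probe-level file was used here, so background and probe effects were taken as the authors left them. The number of arrays limits the precision: the spread came from 2 groups of 2 arrays, with 2 residual degrees of freedom and 4.94 prior degrees of freedom.

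Probe sets were named through a probe table taken from GEO's platform annotation, which listed 25335 of them with a gene. A single symbol was given for 23521 probe sets and several for 1814, and 16010 were not listed with a symbol and stayed unnamed. Entrez identifiers of 23328 single-symbol probe sets were found in a RefSeq table of assembly GRCm38.p6, which changed 0 symbols, and 193 were not found. The build of the array design is not given in the sources used here, so no coordinates are printed. A gene was tested if it had a single symbol and a log2 level of at least 5 on at least 1 array. Of several probe sets of 1 gene (1082 genes) the brightest on average was used. This left 11127 of 22180 genes.

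Differences were tested with limma 3.58.1 in R 4.3.3. All 7 arrays entered 1 fit with 5 groups, with moderated variances, 2-sided tests and Benjamini-Hochberg adjustment over all genes tested. A gene was called at an adjusted p under 0.05. Errors beside log2 differences are standard errors from this fit. R848, CpG B and poly I:C had 1 array each, which was assumed to vary like the other groups. Errors and p-values rest on 2 animals.

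Gene lists fixed before the data were examined (22 pathway lists and 12 cell type lists) were tested with limma's camera at a preset correlation between genes of 0.01. They were tested again with a correlation estimated from the residuals and with fry. The latter asks whether a list's genes move one way on balance and does not compare them with other genes. The estimated correlation rests on 2 residual degrees of freedom and called no list in any comparison. Its power was not measured, so how far its p-values speak against a list is not known. Fry called no list either. Camera's p-values at the preset 0.01 are too small for a list whose genes are more strongly correlated than that. The pathway lists cover interferon-stimulated genes, interferon genes, cytokines, chemokines, NF-kB targets, immediate-early genes, coagulation, endosomal TLR genes, NADPH oxidase, the inflammasome, MHC class I and II, costimulation, JAK-STAT feedback, ER stress, heat shock, glycolysis, sterol synthesis, apoptosis, proliferation, ribosomal proteins and mitochondrially encoded genes. The cell type lists cover monocytes, B cells, T cells, NK cells, neutrophils, erythroid cells, platelets, plasmacytoid and conventional dendritic cells, red pulp macrophages, basophils with mast cells and eosinophils, and endothelial with stromal cells. A list needed 3 tested genes, which left 33 lists.

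Named genes followed a rule set before the data were examined. For HL7G against unstimulated these were the 15 largest rises and 10 largest falls among called genes with the same sign in both mice. For each agonist they were the 8 largest rises and 4 largest falls, and for each direct difference the 6 largest each way, given as values where none was called. In each list up to 4 members with the largest change were named. Tnf, Il1b, Il6, Il12b, Ifnb1, Irf7, Ifit1, Isg15, Cxcl10, Ccl2, Ccl5, F3, Procr, Tlr3, Tlr7, Tlr8 and Tlr9 were always named. Predicted loci, small RNAs, olfactory and vomeronasal receptors and receptor segments were not named by size.

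Arrays with the same mouse number came from the same animal, so the numbers pair the samples. Over the genes tested, the unstimulated and HL7G differences between mouse 2 and mouse 1 had r = -0.146. A fit with the mouse as a block was chosen before the data were examined as another setting. Correlations between HL7G and an agonist share the unstimulated arrays, so unchanged groups were simulated against those arrays in 100 draws (20 of them with a fit), and the correlation was repeated with no shared array.

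Other settings, chosen before the data were examined, changed the level filter, the use of several probe sets, the normalization (quantile normalization again, median centring), the variance trend, the fold threshold and the arrays left out in turn. The unstimulated arrays read several abundant transcripts low, and 3 further normalizations were therefore added after seeing the data. These were cyclic loess on the tested genes, cyclic loess on all probe sets and quantile normalization of the tested genes. A comparison of each list with 10000 random lists of the same size, matched on level over 20 bins of the arrays outside the comparison, and a crossed pairing were also added after seeing the data. With the deposited values as the main setting, 6 normalizations were compared in all.

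The fit was tested on simulated data for 11127 genes of which 200 were changed, 100 by 1 and 100 by 3 on the log2 scale. For HL7G against unstimulated it recovered 29 of 100 at 1 and 100 of 100 at 3, with 15 unchanged genes called. For R848 against unstimulated it recovered 3 and 99 of 100, with 11 unchanged genes called. For HL7G against R848 it recovered 20 and 99 of 100, with 9 unchanged genes called. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.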

Results

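Gene expression was measured in splenic monocytes of 2 mice with 5 treatment groups on 7 arrays. The unstimulated and HL7G groups had 1 array from each mouse (n = 2). HL7G is a monoclonal antiphospholipid antibody, of the kind found in antiphospholipid syndrome, and was given at 400 ng/ml. The groups treated with R848 (2 µg/ml, an agonist of TLR7), CpG B (2.5 µM, an oligonucleotide agonist of TLR9) and poly I:C (1 µg/ml, a double-stranded RNA mimic sensed by TLR3) had 1 array each, from mouse 1, and so no replicate of their own. Stimulation lasted 3 h. The cells carried wild-type EPCR, the endothelial protein C receptor encoded by Procr. The comparisons ask how monocytes respond to the antibody and how that response relates to those of the endosomal Toll-like receptor agonists.

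Several monocyte genes were dim in all samples. Ly6c2 and Ccr2, surface markers of classical monocytes, stayed between 3.74 and 4.38 and between 3.76 and 4.09 on the log2 scale, under the level needed for testing. Lyz2, which encodes lysozyme, lay between 4.53 and 7.02, and Cx3cr1, a chemokine receptor of patrolling monocytes, between 5.13 and 6.503. Irf8, a transcription factor of monocyte and dendritic cell development, read 5.44 and 5.42 in the unstimulated samples and 6.71 to 8.49 on the other arrays. The 2 unstimulated arrays read several abundant transcripts low, and these genes were chosen after their values were seen. Actb, the cytoskeletal actin, read 5.02 and 6.81 in the unstimulated samples of mouse 1 and mouse 2 and 7.77 to 9.34 on the other 5 arrays. B2m, the light chain of MHC class I, read 5.74 and 7.90 against 9.23 to 10.3, and the translation factor Eef1a1 read 6.61 and 9.46 against 10.2 to 10.8. Gapdh, a glycolytic enzyme, went the other way, at 9.13 and 8.75 against 7.73 to 8.32. Across genes, which are not independent replicates, r was 0.849 between the unstimulated arrays and 0.870 between the HL7G arrays. The unstimulated and HL7G arrays of mouse 1 had r = 0.305, and those of mouse 2 had r = 0.744.

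**Figure D1:**
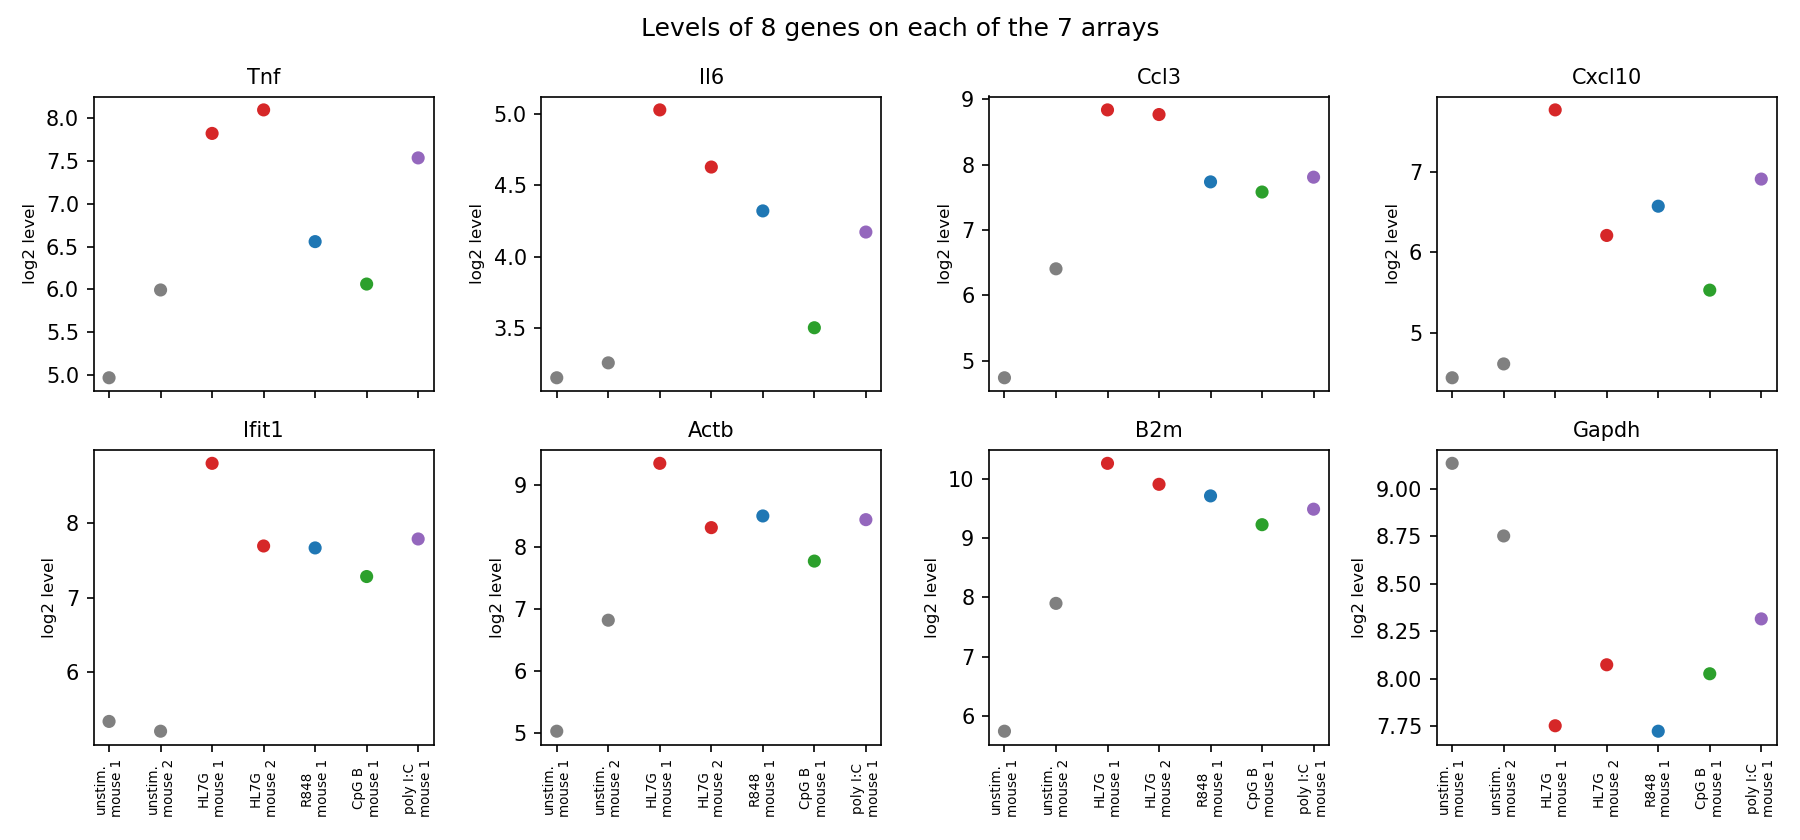
Log2 level of 8 genes (vertical axes, separate scales that do not start at 0) on each of the 7 arrays, with 1 point per array coloured by treatment. Ifit1 lay at 5.33 and 5.20 in the unstimulated samples and at 7.29 to 8.81 with the 4 stimuli, and Actb read 5.02 and 6.81 in the unstimulated samples against 7.77 to 9.34 elsewhere.

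Inflammatory and interferon-response genes were higher after 3 h with HL7G than in the unstimulated samples. Tnf, the cytokine tumour necrosis factor, rose 5.57-fold (log2 difference 2.48 ± 0.35 SE, n = 2 against 2, adjusted p = 0.0120), and Il6, another inflammatory cytokine, rose by 1.62 ± 0.23 (adjusted p = 0.0120). The chemokine Ccl3, which draws in leukocytes, rose 9.38-fold (3.23 ± 0.49, adjusted p = 0.0125). Ifit1, an antiviral protein induced by interferon, rose 7.91-fold (2.98 ± 0.36, adjusted p = 0.0120), and the interferon-inducible Ifi209 had the largest rise of the named genes at 26.1-fold (4.70 ± 0.46, adjusted p = 0.0120). In limma, 2024 of 11127 genes changed, 1814 of them higher and 210 lower, with 4000 at an unadjusted p under 0.05 against 556.4 by chance.

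The other named rises included cell surface, signalling and RNA-binding proteins. Cd69, an early activation marker of leukocytes, rose 13.7-fold (3.78 ± 0.78, adjusted p = 0.0215), and Nampt, which makes a precursor of NAD, rose 11.4-fold (3.51 ± 0.56, adjusted p = 0.0136). Ptprc, which encodes the leukocyte phosphatase CD45, rose by 3.44 ± 0.43, Rap1b, a small GTPase of cell adhesion, by 3.50 ± 0.46, and Samhd1, a nucleotide hydrolase that restricts viruses, by 3.27 ± 0.43 (adjusted p = 0.0120 for each). Parp14, an ADP-ribosyltransferase of the interferon response, rose by 3.35 ± 0.51 (adjusted p = 0.0124). B2m rose by 3.27 ± 0.62 (adjusted p = 0.0187), Ywhaz, a 14-3-3 adaptor protein, by 3.33 ± 0.46 (adjusted p = 0.0120) and Hnrnpu, a nuclear RNA-binding protein, by 3.24 ± 0.51 (adjusted p = 0.0134). Rabggtb (4.60 ± 1.09, adjusted p = 0.0310), Rps13 (4.60 ± 0.30, adjusted p = 0.0120), Rps20 (3.63 ± 0.57, adjusted p = 0.0129) and Ncl (3.36 ± 0.61, adjusted p = 0.0166) also rose. These 4 genes, like Gnl3, which is named with CpG B, host small nucleolar RNAs in their introns, and the probe locations were not given, so whether the host transcript or the small RNA was read is not settled. Loess on the tested genes kept these calls but lowered Rap1b to 2.26, Ncl to 2.03, Parp14 to 2.02, Samhd1 to 1.91, Ywhaz to 1.84, Hnrnpu to 2.09, B2m to 1.72, Ccl3 to 1.90, Ifit1 to 1.81 and Tnf to 1.55. With the mean of all probe sets of a gene Rps20 had 1.99 and Ywhaz 1.27. Ptprc, like Actb and B2m, read low in the unstimulated samples. It was at 4.06 in mouse 1 and 5.44 in mouse 2, against 6.86 to 8.30 on the other arrays. The rises of Ptprc and B2m may therefore partly reflect that low reading, which was not separated from a response to HL7G.

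The named falls were smaller than the named rises in the deposited values. Sly and Srsy, members of multicopy families on the Y chromosome whose copies can share probes, had log2 differences of -1.83 ± 0.44 (adjusted p = 0.0312) and -1.75 ± 0.32 (adjusted p = 0.0178). Zscan4b, a zinc finger gene of the early embryo, had -1.80 ± 0.27 (adjusted p = 0.0124). Pla2g10os (-1.67), Srsx (-1.64), Trim43c (-1.60), Astx5 (-1.57), Morf4l1-ps1 (-1.48), Scgb2b20 (-1.47) and Zfp992 (-1.40) completed the 10 largest falls, with adjusted p between 0.0134 and 0.0271. After loess on the tested genes Srsy (-3.19), Astx5 (-3.12) and Zfp992 (-2.55) were lower still. They had -2.92, -2.85 and -2.23 after quantile normalization of the tested genes.

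Leaving out 1 array left 1 residual degree of freedom, so a lost call need not mean a smaller difference. The calls with HL7G depended on the mouse 1 unstimulated array. Without it 2 genes were called, against 862 without the mouse 2 unstimulated array, 1342 without the mouse 1 HL7G array and 3298 without the mouse 2 HL7G array. Of 33 named called genes, 32 lost the call without the mouse 1 unstimulated array and none changed direction. There Tnf had 1.96 and Ifit1 3.05 (adjusted p = 0.0878 for both). Ifi209 had 4.24 and Rabggtb 2.61 (adjusted p = 0.0877 for both), and Il1b had 1.42 (adjusted p = 0.127). Without the mouse 2 unstimulated array 8 named genes lost the call, Cd69 (3.61, adjusted p = 0.0740), Cxcl10 (2.55, 0.0543), Isg15 (1.61, 0.135), Tlr7 (1.36, 0.105), Sly (-1.22, 0.118), Pla2g10os (-1.502, 0.115), Morf4l1-ps1 (-1.44, 0.0537) and Zfp992 (-1.01, 0.127). Without the mouse 1 HL7G array Sly and Zfp992 lost it (-1.45 and -1.19), and Cd69, Isg15 and Pla2g10os kept it at 2.39, 1.26 and -1.11. A variance trend ended the calls of Il6 (adjusted p = 0.139), Zscan4b (0.111), Astx5 (0.0640) and Tlr7 (0.0510). Testing only genes with a mean level of at least 6 ended those of Rabggtb (0.0503) and Sly (0.0511). The share of higher calls was 89.6%. It was 64.8% when each probe set was tested on its own, 68.7% (1373 higher, 625 lower) after loess on the tested genes and 57.6% (1398 higher, 1029 lower) after quantile normalization of the tested genes. The median over all genes was 0.06, and it became 0.19 with median centring, -0.08 with loess on the tested genes and -0.12 with quantile normalization of them.

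The HL7G differences were also compared between the mice. Across genes, the HL7G differences of mouse 1 and mouse 2, which share no array, had r = 0.779 and rho = 0.748, and 78.2% of genes had the same sign. At least 2-fold differences were seen in both mice for 957 higher and 74 lower genes, and 4 genes moved 2-fold in opposite directions. Tnf differed by 2.85 in mouse 1 and 2.10 in mouse 2, Ifit1 by 3.47 and 2.49, and Ccl3 by 4.10 and 2.36. Differences were wider in mouse 1, with an SD over genes of 1.05 against 0.60.

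**Figure D2:**
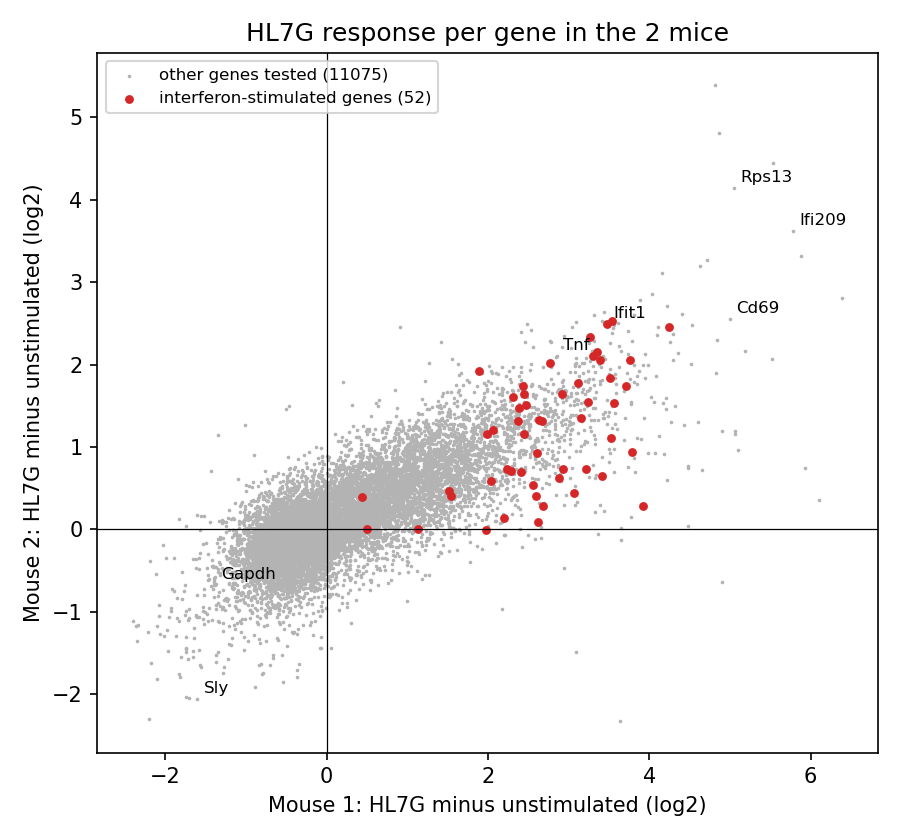
HL7G minus unstimulated on the log2 scale in mouse 1 (horizontal axis) and mouse 2 (vertical axis), with 1 point per tested gene and the 52 interferon-stimulated genes in red. The median of the red points was 2.65 in mouse 1 and 1.18 in mouse 2.

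Interferon-stimulated genes, which encode antiviral effectors and sensors, rose as a group with HL7G. Of 52 tested members 52 lay above 0, 30 were called higher and none lower, and 42 were higher when adjusted over the list alone. The median difference was 1.97, above all 10000 random lists matched on level (camera adjusted p = 2.48e-12, adjusted p = 0.601 with an estimated correlation). Parp14, Igtp (3.03 ± 0.34, an interferon-inducible GTPase), Ifit1 and Ifih1 (2.91 ± 0.47, the cytosolic RNA sensor MDA5) led the group. Isg15, a ubiquitin-like modifier, rose by 1.96 ± 0.47 (adjusted p = 0.0319). Irf7, a transcription factor that amplifies interferon production, had 1.97 ± 0.65 and was not called (adjusted p = 0.0763), although it was with the mouse as a block (adjusted p = 0.0362) and with a variance trend (0.0459). Irf7 differed by 3.22 in mouse 1 and 0.73 in mouse 2. It had 3.11 and was called without the mouse 2 HL7G array (adjusted p = 0.000563), without the mouse 1 HL7G array it had 0.83 (adjusted p = 0.0756), and after loess on the tested genes it had 1.22 (adjusted p = 0.123). The list median was 1.21 without the mouse 1 HL7G array (camera adjusted p = 2.32e-14). The genes of interferon itself were not higher. Ifnb1 stayed at or under 3.58 on every array and was not tested. The list of type I and III interferon genes had a median of -0.55 over 7 members (camera adjusted p = 0.00590, adjusted p = 0.601 with an estimated correlation), with Ifna4 (-1.17 ± 0.29) and Ifna6 (-0.94 ± 0.23) called lower, 2 also when adjusted over the list alone. That median was -0.33 without the mouse 1 unstimulated array. The list's medians on the 7 arrays lay between 5.28 and 6.26, little above the level of 5 needed for testing. They were lower with all 4 stimuli than in the unstimulated samples, so the fall is not particular to HL7G.

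NF-kB targets and feedback regulators, the early response to inflammatory signals, shifted higher with a median of 1.52 over 22 members (camera adjusted p = 7.23e-07, adjusted p = 0.601 with an estimated correlation). Of these 15 were called higher, and 20 when adjusted over the list alone. Nfkbiz, a nuclear co-regulator, rose by 2.99 ± 0.56, and the subunits Rel and Nfkb2 rose by 2.80 ± 0.47 and 2.41 ± 0.41. The cytokine list had 5 of 12 members called higher (5 adjusted over the list alone), Tnf, Il6, Il1b (2.16 ± 0.48), Il1a (1.82 ± 0.23) and Il12a (0.97 ± 0.22). Il12b had 0.26 ± 0.23 (adjusted p = 0.433), with 0.08 without the mouse 1 HL7G array and 0.43 without that of mouse 2. The list median was 0.67 (camera adjusted p = 0.0419, adjusted p = 0.601 with an estimated correlation). The call ended without the mouse 1 unstimulated array (0.70, adjusted p = 0.0627) or the mouse 1 HL7G array (0.20, adjusted p = 0.145) and under every rescaling tried (adjusted p between 0.0546 and 0.0749). Il1b lost its call after loess and after quantile normalization of the tested genes (1.18, adjusted p = 0.109, and 1.52, adjusted p = 0.0797). Chemokines had 5 of 9 members called higher (5 adjusted over the list alone), with a median of 0.93 (camera adjusted p = 0.00590, adjusted p = 0.601 with an estimated correlation). Besides Ccl3 these were Cxcl10 (2.46 ± 0.47), Ccl5 (2.29 ± 0.31), Ccl4 (1.57 ± 0.36) and Ccl9 (0.93 ± 0.21). Ccl2 had 0.40 ± 0.23 (adjusted p = 0.241), and 0.25 without the mouse 1 unstimulated array. Ccl5 had 0.88 after loess and 1.48 after quantile normalization of the tested genes. The chemokine median was 0.41 and 0.51 there, with both calls kept. The NF-kB median was 1.01 after that loess.

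Immediate-early genes, transcribed within minutes of a signal, shifted higher with a median of 0.85 over 26 members, of which 7 were called and 13 passed when adjusted over the list alone (camera adjusted p = 0.00602, adjusted p = 0.601 with an estimated correlation). Myc, a growth regulator, rose by 2.35 ± 0.45, Zfp36, which destabilises cytokine mRNA, by 2.03 ± 0.23, and Junb by 1.78 ± 0.28, while Jun had 1.84 ± 0.57 (adjusted p = 0.0648). The median was 0.49 without the mouse 1 HL7G array (adjusted p = 0.00607), and loess on the tested genes ended the call (0.24, adjusted p = 0.0644). JAK-STAT feedback genes had 5 of 8 members called, both overall and adjusted over the list alone, including Pim1 (2.22 ± 0.44) and Jak2 (2.11 ± 0.30). Their median of 0.86 was not called in the main fit and was called with the mouse as a block (camera adjusted p = 0.0547, 0.0359 with the block, and adjusted p = 0.601 with an estimated correlation).

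Endosomal Toll-like receptor pathway genes, which sense nucleic acids, shifted higher with 7 of 15 members called and 11 when adjusted over the list alone (median 0.73, camera adjusted p = 0.00119, adjusted p = 0.601 with an estimated correlation). Tlr7 rose by 1.496 ± 0.32 (adjusted p = 0.0233), Unc93b1, the chaperone that carries these receptors to endosomes, by 2.07 ± 0.33, Hsp90b1 by 2.25 ± 0.32 and Ctss, a protease that processes them, by 2.14 ± 0.46. Tlr9 had 0.34 ± 0.28 (adjusted p = 0.401), with 0.00836 without the mouse 1 HL7G array and 0.68 (adjusted p = 0.0877) without that of mouse 2, and Tlr3 and Tlr8 stayed at or under 4.41 and 4.03 and were not tested. The list median was 1.09 without the mouse 2 HL7G array. NADPH oxidase and oxidant genes, which produce and handle superoxide, had 7 of 11 members called, and 9 when adjusted over the list alone (median 1.02, camera adjusted p = 0.009995, adjusted p = 0.601 with an estimated correlation). The catalytic subunit Cybb rose by 2.73 ± 0.38, the haem oxygenase Hmox1 by 1.43 ± 0.36 and the cytosolic subunit Ncf1 by 1.41 ± 0.33. Loess on the tested genes ended the list's call (0.50, adjusted p = 0.0689). Inflammasome genes had 3 of 8 members called, Casp8 (2.59 ± 0.32), Casp4 (1.55 ± 0.38) and Gsdmd (1.07 ± 0.27), and 4 when adjusted over the list alone, and the list was not called (0.59, camera adjusted p = 0.132). Coagulation and protein C receptor genes had a median of 0.10 (camera adjusted p = 0.982). F3, which encodes tissue factor, had -0.32 ± 0.22 (adjusted p = 0.320), and -0.19 without the mouse 1 HL7G array. Procr had -0.50 ± 0.21 (adjusted p = 0.143). Of 12 members only P4hb, a protein disulfide isomerase, was called (1.12 ± 0.28), with 0 passing when adjusted over the list alone.

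Antigen presentation genes were higher in the HL7G samples, as were B cell markers (8 of 11 called, median 1.33), and B cells also express MHC class II. Of 14 MHC class I pathway genes 11 were called higher and 12 when adjusted over the list alone (median 1.51, camera adjusted p = 5.56e-05, adjusted p = 0.601 with an estimated correlation), with B2m, H2-T23 (2.21 ± 0.38) and H2-K1 (2.13 ± 0.46) at the top. MHC class II genes had 3 of 6 called, both overall and adjusted over the list alone, H2-Ab1 (2.72 ± 0.31), H2-Aa (2.21 ± 0.48) and H2-Eb1 (1.10 ± 0.24), with a median of 1.06 (camera adjusted p = 0.0286, adjusted p = 0.601 with an estimated correlation). Among level-matched random lists this lay at the percentile 92.6 in mouse 1 and 75.2 in mouse 2. The MHC class II call ended after both loess settings (adjusted p = 0.0965 and 0.0548) and quantile normalization of the tested genes (adjusted p = 0.0551). Costimulatory molecules had 2 of 8 called, Cd274 (2.00 ± 0.44), which encodes PD-L1, and Cd83 (1.47 ± 0.40), and 5 when adjusted over the list alone. Their median was 1.03 (camera adjusted p = 0.0278, adjusted p = 0.601 with an estimated correlation) and 0.61 without the mouse 1 HL7G array (adjusted p = 0.0506).

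Ribosomal protein genes read low on the unstimulated arrays, as several abundant transcripts did, with medians of 6.30 and 7.10 against 7.69 to 8.49 on the other arrays. Ribosomal protein genes had 11 of 16 members called higher, and 13 higher and 1 lower when adjusted over the list alone (median 1.92, camera adjusted p = 0.000584, adjusted p = 0.601 with an estimated correlation), led by Rpl4 (2.91 ± 0.46) and Rpl7 (2.85 ± 0.43). After loess on the tested genes the median was 0.62 (adjusted p = 0.0680). Mitochondrially encoded genes of the respiratory chain did not read low on the unstimulated arrays. Array medians were 11.19 and 11.18 there, 11.12 to 11.46 with the agonists and 11.93 and 12.18 with HL7G. Of the 9 mitochondrially encoded genes 5 were called, and 7 when adjusted over the list alone, including ND2 (1.07 ± 0.29) and COX3 (1.03 ± 0.27). Their median was 0.93 (camera adjusted p = 0.0131, adjusted p = 0.601 with an estimated correlation), lower than in most level-matched random lists (percentile 18.1), and it turned to -0.69 after loess on the tested genes (adjusted p = 0.116). The call also ended without the mouse 2 HL7G array (0.90, adjusted p = 0.0841), after quantile normalization again (0.75, adjusted p = 0.0762), after loess on all probe sets (0.27, adjusted p = 0.913) and after quantile normalization of the tested genes (0.34, adjusted p = 0.320). Heat shock genes had 2 of 7 called, the chaperones Hspa8 (2.32 ± 0.34) and Hspe1 (0.99 ± 0.28), and 6 when adjusted over the list alone (median 0.99, camera adjusted p = 0.0396, adjusted p = 0.601 with an estimated correlation). The heat shock call ended without the mouse 1 unstimulated array (0.87) and without the mouse 1 HL7G array (0.52). Median centring (1.09), loess on all probe sets (0.99) and loess on the tested genes (0.74) ended it too (adjusted p between 0.0610 and 0.0712). ER stress (0.33), glycolysis (0.47), sterol synthesis (0.34), apoptosis (0.60) and proliferation genes (0.49) were not called as lists (camera adjusted p between 0.0742 and 0.366). Their called members included Calr (2.30 ± 0.31), Atf4 (2.01 ± 0.41), Pfkp (1.33 ± 0.26), Hmgcs1 (1.39 ± 0.29) and Mcl1 (1.87 ± 0.31), a survival protein, whereas Gapdh fell by 1.03.

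Markers of lymphocytes were higher in the HL7G samples. Of 11 B cell genes 8 were called higher and 10 when adjusted over the list alone (median 1.33, camera adjusted p = 0.000198, adjusted p = 0.601 with an estimated correlation), among them Fcer2a (1.84 ± 0.44), Ms4a1 (1.75 ± 0.22), which encodes CD20, and the kinase Blk (1.65 ± 0.22). Of 12 T cell genes 6 were called and 7 when adjusted over the list alone (median 0.85, camera adjusted p = 0.00248, adjusted p = 0.601 with an estimated correlation), among them Il7r (2.58 ± 0.43), Cd3g (2.12 ± 0.23) and Cd3d (1.91 ± 0.30). Monocyte genes had a median of -0.09 and a mean of 0.29, which differ in sign (camera adjusted p = 0.963), and 2 of 11 were called, Irf8 (2.17 ± 0.52) and Lyz2 (1.79 ± 0.34). No call was made for NK cells (-0.33), neutrophils (-0.34), erythroid cells (-0.18), platelets (-0.35), plasmacytoid dendritic cells (0.40), conventional dendritic cells (0.50), red pulp macrophages (0.00) or endothelial and stromal cells (-0.23), with camera adjusted p between 0.1504 and 0.967. Within these lists Ccr7 (1.52 ± 0.34) and Pecam1 (1.22) were called. Basophil, mast cell and eosinophil genes had 0 members at the level needed.

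Not all called lists stood out from random lists matched on level. The percentiles of the HL7G medians in mouse 1 and mouse 2 were 100 and 100 for interferon-stimulated genes, 99.99 and 99.7 for NF-kB targets, 98.1 and 99.9 for B cell genes, 99.1 and 99.9 for endosomal TLR genes and 98.6 and 97.6 for ribosomal protein genes. They were 98.3 and 95.51 for immediate-early genes, 94.97 and 99.3 for MHC class I genes, 91.9 and 99.9 for T cell genes, 98.99 and 90.6 for costimulatory genes and 69.3 and 98.3 for chemokines. Lower ones were found for NADPH oxidase genes (78.8 and 94.9), cytokines (94.9 and 66.4), heat shock genes (95.01 and 76.7) and mitochondrially encoded genes (5.10 and 54.5), and type I and III interferon genes lay at 0.29 and 2.20. After loess and after quantile normalization of the tested genes the medians of MHC class I genes were 0.69 and 0.97, those of T cell genes 0.52 and 0.48 and those of type I and III interferon genes -1.34 and -1.13, with the calls kept.

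**Figure D3:**
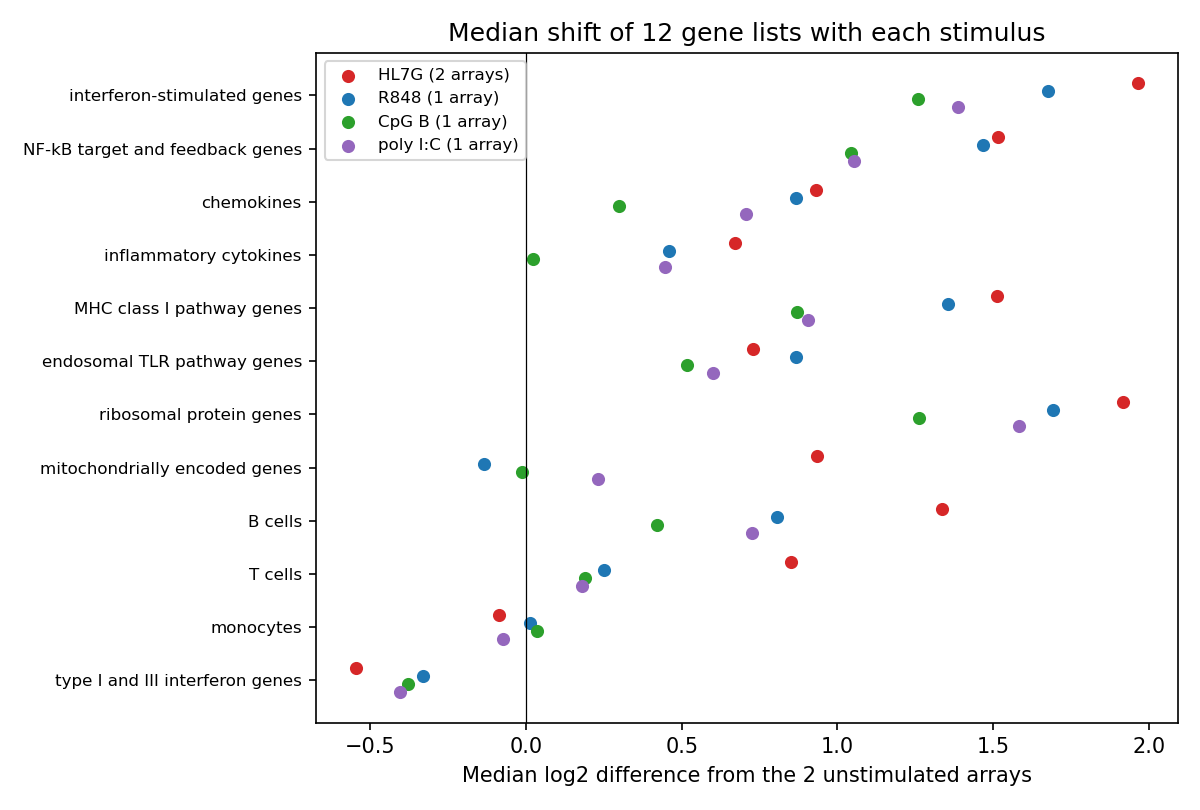
Median log2 difference of 12 gene lists from the 2 unstimulated arrays (horizontal axis) with each stimulus, as 1 point per list and stimulus. The interferon-stimulated genes had medians of 1.97 with HL7G, 1.68 with R848, 1.26 with CpG B and 1.39 with poly I:C, and the mitochondrially encoded genes turn below 0 with HL7G after loess on the tested genes.

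R848 was compared with the unstimulated arrays as a TLR7 reference. Interferon-stimulated genes had the clearest group shift, with 51 of 52 members above 0, a median of 1.68 and 25 higher when adjusted over the list alone (camera adjusted p = 1.23e-11, adjusted p = 0.690 with an estimated correlation). NF-kB targets had a median of 1.47 and 15 of 22 higher when adjusted over the list alone (camera adjusted p = 2.06e-07, adjusted p = 0.690 with an estimated correlation), with Nfkbiz at 3.45 ± 0.68 and Gadd45b, a stress sensor, at 2.67 ± 0.68. Heat shock genes had a median of 1.53 with 4 of 7 higher when adjusted over the list alone (camera adjusted p = 0.0319, adjusted p = 0.690 with an estimated correlation), including Hspa8 (2.24 ± 0.42) and Hsph1 (1.80 ± 0.34). That list lost its call after loess on all probe sets (adjusted p = 0.0538).

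No single gene was called in limma for R848 against unstimulated, with 2551 genes at an unadjusted p under 0.05 and a smallest adjusted p of 0.0855. With the mouse as a block 5 were called, Rny1, Rps13 (3.83 ± 0.41, adjusted p = 0.0398), Rps20 (3.84 ± 0.43, adjusted p = 0.0427) and Snord70 higher and Vmn1r129 lower, of which Rny1, Snord70 and Vmn1r129 were named after their values were seen. By size Ifi209 (4.24 ± 0.57), Rabggtb (3.97), Ncl (3.67), Rps13 (3.64), Cd69 (3.62), Nfkbiz, Nampt (3.42) and Rps20 (3.19) led, and Sly (-2.68), Btbd35f5 (-2.44), Pla2g10os (-2.21) and Stfa1 (-2.05) were lowest. Tnf had 1.08 ± 0.43, Il6 had 1.11 ± 0.29, Ifit1 had 2.40 ± 0.45 and Cxcl10 had 2.05 ± 0.58. After loess on the tested genes Tnf had 0.21, Ifit1 1.29 and Ncl 2.41, and Il6 had 0.68 after quantile normalization of the tested genes. Tnf was at 0.56 without the mouse 1 unstimulated array and 1.59 without that of mouse 2. Rabggtb was at 1.98 (adjusted p = 0.329) and 5.96 (adjusted p = 0.00927) there, and Rps20 was at 1.97 with the mean of its probe sets. Other settings gave 657 calls after quantile normalization again, 95 with a variance trend, 51 after loess and 576 after quantile normalization of the tested genes, 137 without the mouse 2 unstimulated array and 1542 without either HL7G array, where 1 group of 2 is left to set the spread. The loess split was 9 higher and 42 lower.

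Further lists were called for R848. MHC class I genes (1.35, camera adjusted p = 6.55e-05), ribosomal protein genes (1.69, 0.00111), endosomal TLR genes (0.87, 0.000830), B cell genes (0.80, 0.00160), NADPH oxidase genes (0.87, 0.0316), MHC class II genes (0.96, 0.0477) and ER stress genes (0.61, 0.0230) shifted higher, and erythroid genes lower (-0.45, 0.0338), each with adjusted p = 0.690 with an estimated correlation. Adjusted over the list alone 11 of 14 MHC class I, 4 of 15 endosomal TLR, 5 of 11 NADPH oxidase, 3 of 6 MHC class II, 3 of 11 ER stress and 2 of 11 B cell genes were higher. Ribosomal protein genes had 11 of 16 higher and 1 lower, with a median of 1.06 without the mouse 1 unstimulated array and 0.25 after loess on the tested genes (adjusted p = 0.405). The same loess ended the calls of B cell (0.40, adjusted p = 0.0678), NADPH oxidase (0.38, adjusted p = 0.152) and MHC class II genes (0.53, adjusted p = 0.106). Loess on all probe sets ended the calls of NADPH oxidase (adjusted p = 0.0538), MHC class II (0.0781) and erythroid genes (0.0839). Median centring ended those of MHC class II (0.0786) and erythroid genes (0.0980), the latter also lost after loess on the tested genes (0.0903). The loess on the tested genes left the calls of NF-kB (0.85), MHC class I (0.38) and heat shock genes (0.84) at smaller medians. ER stress and erythroid genes lost the call with the mouse as a block (adjusted p = 0.0539 and 0.0831). Erythroid genes also lost it without the mouse 2 unstimulated array (-0.48, adjusted p = 0.0928), and MHC class II genes without the mouse 1 unstimulated array (0.72, adjusted p = 0.0550).

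CpG B was compared as a TLR9 reference, with smaller medians in the same leading lists. Interferon-stimulated genes had a median of 1.26 and 15 higher when adjusted over the list alone (camera adjusted p = 2.04e-11, adjusted p = 0.782 with an estimated correlation). NF-kB targets had a median of 1.04 and 10 of 22 higher when adjusted over the list alone (camera adjusted p = 6.26e-06, adjusted p = 0.782 with an estimated correlation), with Nfkbiz at 3.68 ± 0.68. Inflammatory cytokines had a median of 0.02 (camera adjusted p = 0.942), with Tnf at 0.58 ± 0.43, Il1b at 0.58 ± 0.59 and Il6 at 0.30 ± 0.29. Tnf and Il1b turned below 0 after loess on the tested genes (-0.0425 and -0.0814), as Il6 did after quantile normalization of the tested genes (-0.49). Tnf and Il1b were at 0.0691 and -0.16 without the mouse 1 unstimulated array and at 1.09 and 1.32 without that of mouse 2. Costimulatory genes had a median of 0.95 (camera adjusted p = 0.0165, adjusted p = 0.782 with an estimated correlation), with Cd44, a hyaluronan receptor, at 1.49 ± 0.37 as the 1 member higher when adjusted over the list alone.

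No gene was called in limma for CpG B against unstimulated, also with the mouse as a block, with 1370 at an unadjusted p under 0.05 and a smallest adjusted p of 0.136. Ifi209 (4.70 ± 0.57), Rabggtb (3.87), Nfkbiz, Rps13 (3.64), Phip (3.52), Gnl3 (3.45), Hnrnpu (3.37) and Ncl (3.37) were highest, and Btbd35f5 (-1.40), Fabp5 (-1.40), Btbd35f12 (-1.39) and Zscan4b (-1.36) lowest. Gnl3 hosts small nucleolar RNAs, so the doubt about its probe set holds here too. Rabggtb was at 1.88 (adjusted p = 0.817) without the mouse 1 unstimulated array and 5.86 (adjusted p = 0.00984) without that of mouse 2, and Btbd35f5 was at -2.13 and -0.68. Other settings gave 4 calls after quantile normalization again, 2 with a variance trend, 2 after loess and 120 after quantile normalization of the tested genes, 86 without the mouse 2 unstimulated array and 528 without either HL7G array. Ribosomal protein (1.26, camera adjusted p = 9.81e-05), MHC class I (0.87, 0.000393), endosomal TLR (0.52, 0.00441), heat shock (0.70, 0.0139), ER stress (0.68, 0.0165) and apoptosis genes (0.62, 0.0291) shifted higher and type I and III interferon genes lower (-0.38, 0.0394), each with adjusted p = 0.782 with an estimated correlation. Adjusted over the list alone 8 of 16 ribosomal protein, 2 of 7 heat shock and 1 each of the endosomal TLR, ER stress and apoptosis genes were higher, and 0 MHC class I or interferon genes changed. Loess on the tested genes ended the calls of ribosomal protein (0.45, adjusted p = 0.185) and MHC class I genes (0.23, adjusted p = 0.0557). It left costimulatory genes called at 0.63 and interferon genes at -0.61. Without the mouse 1 unstimulated array the interferon genes were at -0.23 (adjusted p = 0.205). Without the mouse 2 unstimulated array apoptosis genes were at 0.56 (adjusted p = 0.0679) and ER stress genes at 0.40 (adjusted p = 0.0489). B cell genes were called with the mouse as a block (0.42, adjusted p = 0.133, 0.0187 with the block, and adjusted p = 0.798 with an estimated correlation).

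Poly I:C was compared as a TLR3 reference. Tlr3 itself read 3.63 on that array, under the level needed for testing, and the receptor involved was not tested. Interferon-stimulated genes and chemokines were higher with poly I:C than in the unstimulated samples. The former had a median of 1.39 and 20 of 52 higher when adjusted over the list alone (camera adjusted p = 6.14e-18, adjusted p = 0.550 with an estimated correlation), with Ifit1 at 2.52 ± 0.45 and Usp18, a brake on interferon signalling, at 2.88 ± 0.59. Chemokines had a median of 0.71 and 4 of 9 higher when adjusted over the list alone (camera adjusted p = 0.000389, adjusted p = 0.550 with an estimated correlation), Cxcl10 (2.38 ± 0.58), Ccl3 (2.24 ± 0.60), Ccl4 (1.69 ± 0.44) and Ccl5 (1.49 ± 0.38). Tnf, at 2.05 ± 0.43, was the 1 cytokine higher when adjusted over the list alone, and the cytokine list had a median of 0.45 (camera adjusted p = 0.0158, adjusted p = 0.550 with an estimated correlation). That call ended without the mouse 1 unstimulated array (0.47, adjusted p = 0.0524) and after quantile normalization of the tested genes (0.35, adjusted p = 0.0524).

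No gene was called in limma for poly I:C against unstimulated, with 1054 at an unadjusted p under 0.05 and a smallest adjusted p of 0.225. A fit with the mouse as a block called 2, the small RNAs Rny1 and Snord1b, named after their values were seen. The largest differences were those of Ifi209 (4.61 ± 0.57), Rabggtb (3.72), Cd69 (3.71), Rps13 (3.39), Gbp8 (3.27), Rps20 (3.08), Parp14 (3.01) and Nampt (2.93), and of Sly (-1.23), Zfp972 (-1.18), Unc93a2 (-1.14) and Srsy (-1.12). Rabggtb was at 1.74 (adjusted p = 0.9996) without the mouse 1 unstimulated array and 5.71 (adjusted p = 0.0104) without that of mouse 2. Sly was at -0.62 without the mouse 2 unstimulated array, and Srsy at -0.68 without that of mouse 1. After loess on the tested genes Srsy had -2.27, Parp14 2.00 and Ifit1 1.67, and after quantile normalization of them Srsy had -1.99 and Zfp972 -1.82. Other settings gave 3 calls after quantile normalization again, 2 with a variance trend, 11 after quantile normalization of the tested genes, 89 without the mouse 2 unstimulated array and 198 without either HL7G array. NF-kB targets (1.05, camera adjusted p = 2.13e-08), ribosomal protein (1.58, 5.74e-06), MHC class I (0.90, 2.42e-05), B cell (0.73, 4.22e-05), endosomal TLR (0.60, 0.000321), JAK-STAT feedback (0.65, 0.00695), MHC class II (0.67, 0.00935), NADPH oxidase (0.41, 0.0132), heat shock (0.55, 0.0132), costimulatory (0.57, 0.0220) and immediate-early genes (0.33, 0.0338) shifted higher and type I and III interferon genes lower (-0.40, 0.0132), each with adjusted p = 0.550 with an estimated correlation. Adjusted over the list alone 8 NF-kB, 10 ribosomal protein, 1 MHC class II and 1 heat shock gene were higher, and 0 members of the other lists in that group changed. With the mouse as a block costimulatory and immediate-early genes lost the call (adjusted p = 0.0689 and 0.136). Without the mouse 1 unstimulated array so did costimulatory (0.46, adjusted p = 0.0535) and interferon genes (-0.22, adjusted p = 0.0760), and the ribosomal protein median became 0.99. Without the mouse 2 unstimulated array the immediate-early call ended (0.33, adjusted p = 0.161). Loess on the tested genes ended the calls of ribosomal protein (0.38, adjusted p = 0.0797), NADPH oxidase (0.13, adjusted p = 0.171), MHC class II (0.67, adjusted p = 0.0611) and immediate-early genes (0.17, adjusted p = 0.271), the last also lost with median centring (adjusted p = 0.0519) and loess on all probe sets (0.0876). It left the chemokine (0.37), NF-kB (0.67), MHC class I (0.22) and interferon gene calls (-0.63) at other medians.

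The differences with HL7G and with each agonist were compared over all genes. Ifi209, Rabggtb and Rps13 were among the 8 largest differences with all 3 agonists. Across genes the correlation of HL7G and agonist differences was r = 0.884 (rho 0.855) for R848, 0.855 (0.811) for CpG B and 0.872 (0.818) for poly I:C. Unchanged groups simulated as independent noise, with simulated unstimulated arrays in common, gave 0.408, 0.406 and 0.409. That noise holds no low reading of abundant transcripts, so it cannot show what such a reading would give. The covariances were 0.491, 0.392 and 0.362 against simulated values of 0.0369, 0.0367 and 0.0369. With no shared array (mouse 2 for HL7G, mouse 1 for the agonist) r was 0.725, 0.659 and 0.664, and of 1057 genes at least 2-fold higher with HL7G in mouse 2, 1045, 1023 and 1030 (98.9%, 96.8% and 97.45%) lay above 0 with the agonist in mouse 1, against 54.4%, 51.8% and 50.9% of all genes. The sets of called genes had an overlap of 0, as no gene was called for an agonist, with 0 for independent sets and 0.45, 0.25 and 0.25 in simulations. The overlap was 5 for R848 and 2 for poly I:C with the mouse as a block. Part of the excess may come from the shared unstimulated arrays. With no shared array, both unstimulated arrays still read several abundant transcripts low, and the shares over all genes were not matched on level. That comparison therefore cannot separate a response common to HL7G and the agonists from the low reading.

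The direct comparison of HL7G with R848 asked whether the antibody and the TLR7 agonist differed. Mitochondrially encoded genes were higher with HL7G by a median of 0.76, with 4 of 9 passing when adjusted over the list alone (camera adjusted p = 5.56e-07, adjusted p = 0.744 with an estimated correlation), a call that ended after loess on the tested genes (0.69, adjusted p = 0.0749). T cell genes were higher by 0.53, with Cd3g (1.18 ± 0.28), Cd3e (1.11 ± 0.29) and Bcl11b (0.92 ± 0.26) passing when adjusted over the list alone (camera adjusted p = 0.000261, adjusted p = 0.744 with an estimated correlation). Chemokines (0.48, camera adjusted p = 0.00764) and immediate-early genes (0.27, 0.0272) were also higher as lists, each with adjusted p = 0.975 with an estimated correlation and 0 members passing when adjusted over the list alone. Without the mouse 1 HL7G array chemokines were at 0.59 (adjusted p = 0.0964) and immediate-early genes at 0.09 (adjusted p = 0.637). Without the mouse 2 HL7G array they were at 0.92 and 0.50. The former setting sets mouse 2 against mouse 1 and so mixes treatment with animal, and the latter stays within mouse 1. Quantile normalization again, or of the tested genes, also ended the immediate-early call (adjusted p = 0.0631 and 0.121). With the mouse as a block 2 further lists were called, the interferon-stimulated genes (0.25, adjusted p = 0.0948, and 0.63 with 5.13e-10 with the block) and cytokines (0.31, adjusted p = 0.0535, and 0.45 with 0.0239 with the block), both with adjusted p = 0.975 with an estimated correlation. No gene was called in limma, with 567 at an unadjusted p under 0.05 and none called with the block. The largest differences upward were those of Ifit1bl1 (1.90 ± 0.59), the cytokine Il1a (1.69 ± 0.29), Rb1 (1.65), the complement regulator Cd55 (1.62), Gbp4 (1.61) and Tnrc6a (1.59). The largest downward were those of Pax6os1 (-1.41), Zscan4b (-1.39), Trim43b (-1.25), Actg2 (-1.21), Defa21 (-1.04) and Hspd1 (-1.01). Ifit1bl1 was at 1.17, Gbp4 at 0.10 and Hspd1 at -1.80 without the mouse 1 HL7G array, and without that of mouse 2 Gbp4 was at 3.13 and Hspd1 at -0.22.

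HL7G was compared with the single CpG B array, and the cytokine genes Il1a (2.06 ± 0.29), Tnf (1.90 ± 0.43) and Il6 (1.32 ± 0.29) passed when adjusted over the cytokine list alone, whose median difference was 0.45 (camera adjusted p = 0.00146, adjusted p = 0.765 with an estimated correlation). B cell genes had a median of 0.92 with 5 of 11 passing when adjusted over the list alone, led by Blk (1.55 ± 0.26) and Cd79a (1.41 ± 0.32), and mitochondrially encoded genes had 0.78 with 4 of 9 passing (camera adjusted p = 4.70e-05 and 8.39e-05, adjusted p = 0.765 with an estimated correlation for both). Interferon-stimulated (0.68, camera adjusted p = 4.70e-05), chemokine (0.64, 0.000464), T cell (0.59, 0.000631), MHC class I (0.61, 0.00110), immediate-early (0.40, 0.00132), NF-kB (0.43, 0.00330), NADPH oxidase (0.37, 0.0280) and MHC class II genes (0.67, 0.0468) were also higher as lists, each with adjusted p = 0.765 with an estimated correlation and 0 members passing when adjusted over the list alone. With the mouse as a block the interferon-stimulated median was 1.08 and the NF-kB median 0.73. Leaving out the mouse 1 HL7G array sets that of mouse 2 against a CpG B array of mouse 1, which mixes treatment with animal. Most of the list calls ended without the mouse 1 HL7G array. Without it the interferon-stimulated genes turned to -0.15 (adjusted p = 0.246), and NF-kB (0.08, adjusted p = 0.828), cytokine (0.24, adjusted p = 0.0513), immediate-early (0.26, adjusted p = 0.130), NADPH oxidase (0.23, adjusted p = 0.0986), MHC class I (0.35, adjusted p = 0.0986) and MHC class II genes (0.35, adjusted p = 0.160) lost the call. Without the mouse 2 HL7G array the interferon-stimulated, NF-kB, cytokine, immediate-early and NADPH oxidase medians were 1.46, 0.90, 0.68, 0.68 and 0.62. Loess on the tested genes ended the calls of mitochondrially encoded (0.68, adjusted p = 0.135), NADPH oxidase (0.06, adjusted p = 0.110) and MHC class II genes (0.32, adjusted p = 0.0999). Quantile normalization of the tested genes ended those of NF-kB (0.12, adjusted p = 0.104), NADPH oxidase (0.00933, adjusted p = 0.262) and MHC class II genes (0.28, adjusted p = 0.124). NADPH oxidase and MHC class II genes also lost the call after quantile normalization again (adjusted p = 0.0567 and 0.0518). MHC class II genes lost it with median centring (0.0623) and loess on all probe sets (0.0729). With the mouse as a block MHC class II genes lost the call (adjusted p = 0.0732), and endosomal TLR genes (0.33, adjusted p = 0.0520, and 0.0434 with the block) and JAK-STAT feedback genes (0.30, adjusted p = 0.0883, and 0.0134 with the block) gained one, both with adjusted p = 0.765 with an estimated correlation.

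No gene was called in limma for HL7G against CpG B, with 864 at an unadjusted p under 0.05, and the block called 1, the small nucleolar RNA Snord70 (4.34 ± 0.38, adjusted p = 0.0321), named after its value was seen. By size Plekho1 (2.16 ± 0.33), Il1a, the itaconate-producing enzyme Acod1 (2.01 ± 0.31), Ifi205 (2.01 ± 0.40), Rpl9 (1.92) and Ifit1bl1 (1.90) led upward. Krtap5-2 (-2.27 ± 0.50), Coq2 (-1.14), Zc3h12c (-1.09), Gnl3 (-1.08), Ang4 (-1.06) and Cmtm5 (-1.04) led downward. Leaving out the mouse 1 HL7G array put Ifit1bl1 at 1.17, Zc3h12c at -1.90, Gnl3 at -2.02 and Ang4 at -0.23. Without that of mouse 2 Zc3h12c was at -0.27, Gnl3 at -0.15 and Ang4 at -1.90. The doubt about the Gnl3 probe set holds here too.

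Against poly I:C, T cell genes were higher with HL7G by a median of 0.60, with Cd3g (1.68 ± 0.28) passing when adjusted over the list alone (camera adjusted p = 0.000402, adjusted p = 0.822 with an estimated correlation). B cell genes had 0.59, with Blk (1.24 ± 0.26) passing when adjusted over the list alone, and mitochondrially encoded genes 0.56 with 0 passing (camera adjusted p = 0.0243 for both, adjusted p = 0.822 with an estimated correlation). Interferon-stimulated (0.47, camera adjusted p = 0.0211), MHC class I (0.57, 0.0201), NF-kB (0.45, 0.0223) and immediate-early genes (0.36, 0.0257) were higher as lists, each with adjusted p = 0.822 with an estimated correlation and 0 members passing when adjusted over the list alone. Tnf (0.42 ± 0.43) and Cxcl10 (0.08 ± 0.58) differed by about their standard error or less. With the mouse as a block the interferon-stimulated median was 0.84. Leaving out the mouse 1 HL7G array sets that of mouse 2 against a poly I:C array of mouse 1, which mixes treatment with animal. Without the mouse 1 HL7G array the interferon-stimulated genes turned to -0.30 (adjusted p = 2.20e-05), and NF-kB (0.08, adjusted p = 0.828), immediate-early (0.13, adjusted p = 0.750) and MHC class I genes (0.29, adjusted p = 0.373) lost the call. Without the mouse 2 HL7G array B cell (0.47, adjusted p = 0.108) and mitochondrially encoded genes (0.51, adjusted p = 0.206) lost it, and the interferon-stimulated, NF-kB and immediate-early medians were 1.22, 0.96 and 0.61. B cell (0.36, adjusted p = 0.109) and mitochondrially encoded genes (0.48, adjusted p = 0.0890) lost it with the mouse as a block too. Loess on the tested genes ended the calls of NF-kB (adjusted p = 0.0564), immediate-early (0.121), mitochondrially encoded (0.336) and B cell genes (0.121). Quantile normalization of the tested genes ended those of interferon-stimulated (0.08, adjusted p = 0.297), NF-kB (0.18, 0.353), immediate-early (0.10, 0.374), MHC class I (0.32, 0.248) and B cell genes (0.28, 0.503). Immediate-early and B cell genes also lost the call after quantile normalization again (adjusted p = 0.0509 and 0.123), and mitochondrially encoded genes after loess on all probe sets (0.0672).

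No gene was called in limma for HL7G against poly I:C, with 900 at an unadjusted p under 0.05 and none with the block. The RNA helicase Ddx3x (1.94 ± 0.36), Ifi214 (1.78), the cohesin loader Nipbl (1.75), Cd3g, the inhibitory receptor Lilrb4a (1.66) and Chd2 (1.64) led upward. Rbm8a (-1.23), Xlr (-1.21), Klrb1 (-1.13), Atp5l (-1.12), Nlrp5 (-1.08) and Rhbdl1 (-1.07) led downward. Ifi214 was at 0.83 and Nlrp5 at -0.72 without the mouse 1 HL7G array, and without that of mouse 2 Ifi214 was at 2.72 and Atp5l at -0.74.

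The agonists were also compared with one another, on 1 array each from mouse 1. These differences cannot separate treatment from array, and their p-values borrow the spread of the other groups. On the CpG B array cytokines (median -0.37, camera adjusted p = 0.00262) and chemokines (-0.41, 0.00209) read lower than on the poly I:C array, with Tnf at -1.47 ± 0.50 and Cxcl10 at -1.38 ± 0.66, as did B cell (-0.33, 0.00835) and mitochondrially encoded genes (-0.23, 0.0435), while apoptosis genes read higher (0.46, 0.0104), each with adjusted p = 0.984 with an estimated correlation. On the R848 array interferon-stimulated (0.39, camera adjusted p = 0.0253), NF-kB (0.35, 0.0253) and B cell genes (0.50, 0.0202) read higher than on the CpG B array, each with adjusted p = 0.934 with an estimated correlation. Mitochondrially encoded (-0.30) and erythroid genes (-0.42) read lower on the R848 array than on the poly I:C array (camera adjusted p = 0.0427 for both, adjusted p = 0.994 with an estimated correlation). No member of these lists passed when adjusted over the list alone. With the mouse as a block, which leaves these differences as they are and changes the spread, interferon-stimulated genes were called lower with CpG B than poly I:C (-0.23, adjusted p = 0.0958, and 0.00875 with the block), MHC class I genes higher with R848 than CpG B (0.43, 0.0622, and 0.0282), NF-kB genes higher with R848 than poly I:C (0.38, 0.0755, and 0.0442), and the erythroid call ended (0.0524). No gene was called in limma in these 3 comparisons, with 330, 337 and 118 at an unadjusted p under 0.05 for R848 against CpG B, R848 against poly I:C and CpG B against poly I:C and none called with the block. By size, R848 exceeded CpG B most for Abracl (1.53) and Gabarap (1.51), an autophagy protein, and fell short most for Krtap5-2 (-2.30) and Sly (-1.85). R848 exceeded poly I:C most for Ddx3x (1.76) and the chaperone Hsph1 (1.66) and fell short most for Btbd35f5 (-1.71) and Btbd35f1 (-1.63). CpG B exceeded poly I:C most for Krtap5-2 (2.25), Ms4a6b (1.55) and Gnl3 (1.53), where the doubt about the probe set holds as well, and fell short most for Tnf, Chil3 (-1.42), a macrophage chitinase-like protein, and Cxcl10.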

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

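The differences between HL7G and the agonists are listed here because a test of the difference itself passed with the preset correlation. None passed with an estimated one (lowest adjusted p = 0.744), which rests on 2 residual degrees of freedom and whose power was not measured. Of the 2 tests below, the comparison with random lists was written down before it was run, and the comparison of the mouse 2 HL7G array with the mouse 1 agonist arrays was chosen after the result was seen.

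T and B cell markers, but not those of NK cells, read higher on the HL7G arrays than on the agonist arrays. T cell genes, such as the receptor chains Cd3g and Cd3e, had median differences of 0.53 against R848, 0.59 against CpG B and 0.60 against poly I:C. After quantile normalization of the tested genes they had 0.34 against R848 and 0.31 against poly I:C, with the calls kept. B cell genes, such as Blk and Cd79a, had 0.92 against CpG B and 0.59 against poly I:C, with no call against R848. NK cell genes had medians of -0.30 to -0.02 against the agonists with either HL7G array, at percentiles of 5.46 to 42.2. If the HL7G samples held more T and B cells, which may be so since how the monocytes were selected is not given, both lists would lie high among random lists matched on level. T cell genes did, at percentiles of 98.9 or more in both mice, whereas B cell genes against R848, CpG B and poly I:C lay at 87.4, 96.5 and 60.8 with the mouse 1 HL7G array and at 99.8, 100 and 99.99 with that of mouse 2, so this test cannot tell. Array quality on the mouse 1 HL7G array cannot be told apart either: the mouse 2 HL7G array gave differences of 0.45 or more, but all agonist arrays came from mouse 1, so these mix treatment with animal, and unstimulated T and B cell medians were also higher in mouse 2 (5.43 and 5.31) than in mouse 1 (5.21 and 5.08).

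Mitochondrially encoded genes of the respiratory chain were higher with HL7G by medians of 0.76 against R848, 0.78 against CpG B and 0.56 against poly I:C. Loess on the tested genes ended these calls, at medians of 0.69, 0.68 and 0.51. The call against poly I:C also ended with the mouse as a block (median 0.48) and without the mouse 2 HL7G array (0.51). The medians changed little where these calls were lost. Interferon-stimulated genes were higher by 0.68 against CpG B and 0.47 against poly I:C, and by 1.08 and 0.84 with the mouse as a block. They lay at -0.15 and -0.30 without the mouse 1 HL7G array, where HL7G and agonist arrays come from different mice. Inflammatory cytokines were higher by 0.45 against CpG B, and chemokines by 0.48 against R848 and 0.64 against CpG B. NF-kB targets were higher by 0.43 against CpG B and 0.45 against poly I:C, and immediate-early genes by 0.27 against R848, 0.40 against CpG B and 0.36 against poly I:C. Without the mouse 1 HL7G array those NF-kB medians were 0.08 and 0.08 and those of immediate-early genes 0.09, 0.26 and 0.13, with no call. Cytokines against CpG B (0.24) and chemokines against R848 (0.59) lost the call without it too. NADPH oxidase genes (0.37) and MHC class II genes (0.67) were higher against CpG B, and MHC class I genes were higher against CpG B (0.61) and poly I:C (0.57), and none of these 4 was called without that array.

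A signal also lay in probe sets outside the gene comparisons. Of 7747 probe sets without a single gene symbol, 885 passed the test for HL7G against unstimulated, 369 higher and 516 lower.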

How the results depend on the processing

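Of the results that answer a comparison, 217 values under other settings stayed the same and 60 moved. A count of 0 calls under both settings was scored as the same. The comparisons between stimuli had 0 calls in nearly all settings, so for them this score says little about stability. For list medians 641 kept their sign and call, 244 lost the call and 3 turned. For named genes 1918 kept their sign and call status, 50 lost the call, 151 gained one and 19 turned. Among the named genes, 77 of the kept and 1 of the turned were values within mouse 1 alone. These had no call and could only keep or turn their sign. Some settings, such as a variance trend, cannot change a difference or its sign, so these counts overstate stability. A kept sign and call does not mean a kept value: Tnf with R848 went from 1.08 to 0.21 after loess on the tested genes. Where a value moved, the cause was not tested unless given here. HL7G against unstimulated had 457 calls at a mean level of at least 6, where 1337 genes were tested, and 2 to 3298 with 1 array left out. R848 had 5 calls with the mouse as a block, 657 after quantile normalization again, 95 with a variance trend, 51 after loess and 576 after quantile normalization of the tested genes, and 0 to 1542 with 1 array left out. CpG B had 4, 2, 2 and 120 calls in the last 4 of these settings and 0 to 528 with 1 array left out. Poly I:C had 2 with the block, 3 after quantile normalization again, 2 with a trend, 11 after quantile normalization of the tested genes and 0 to 198 with 1 array left out. With the block HL7G against CpG B had 1 call, and the overlap of called genes was 5 for R848 and 2 for poly I:C. With the mice paired as numbered HL7G had 1847 calls (1699 higher, 148 lower), of which 1688 were among the 2024 made without the block. Of the named genes and lists, the block changed no other call than those given beside results. With the pairing crossed, chosen after seeing the data, there were 2322 (2075 higher, 247 lower).

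At least 1.5-fold differences in both mice were seen for 2525 genes, and 2-fold ones at a mean level of at least 6 for 412. Correlations with no shared array were 0.725, 0.659 and 0.664, and that between the mice was 0.729 with no level filter, 0.802 at a mean level of at least 6 and 0.762 after loess on the tested genes. No list was called (0) with an estimated correlation or fry in any comparison that involved HL7G or the unstimulated arrays. After loess on the tested genes 9 lists were called for HL7G against unstimulated and 3 against poly I:C, and 2 against poly I:C after quantile normalization of the tested genes. With 1 array left out 4 to 10 lists were called against R848, 4 to 15 against CpG B and 4 to 8 against poly I:C.

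Loess on the tested genes turned the mitochondrially encoded genes (-0.69) and Tlr9 (-0.0241) with HL7G, Ccl5 with R848 (-0.43), and Tnf (-0.0425), Il1b (-0.0814), Il12b (-0.0297) and Ccl5 (-0.0172) with CpG B. Quantile normalization of the tested genes turned Il6 (-0.49), Il12b (-0.0468) and Tlr7 (-0.0333) with CpG B, and quantile normalization again turned Il12b (-0.00229). Procr with R848 turned with the block (0.0168), median centring (0.0624) and loess on all probe sets (0.0329), and Il12b with CpG B with the block (-0.0940) and within mouse 1 (-0.0157). With 1 array left out the interferon-stimulated genes ranged from -0.15 to 1.46 against CpG B and from -0.30 to 1.22 against poly I:C, Procr with R848 from -0.0577 to 0.0509, Il1b with CpG B from -0.16 to 1.32, Il12b with CpG B from -0.0157 to 0.0169 and Ccl2 with poly I:C from -0.00646 to 0.30. Signal over background limits low genes: Ifnb1, Tlr3 and Tlr8 stayed under the level tested.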

Other observations

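The lymphocyte genes Cd79a, Il7r and Ighm are given here per array, as a description without a test. Cd79a, a signalling chain of the B cell receptor, read 4.99 and 5.596 in the unstimulated samples of mouse 1 and mouse 2, 6.63 and 6.62 with HL7G, 6.10 with R848, 5.21 with CpG B and 6.26 with poly I:C. Il7r, the receptor of a T cell survival cytokine, read 4.35 and 4.59 unstimulated, 7.74 and 6.36 with HL7G, 6.52 with R848, 6.94 with CpG B and 6.38 with poly I:C. Ighm, an immunoglobulin heavy chain and the brightest of the 11 B cell genes tested, was chosen after its values were seen. It read 7.80 and 8.66 unstimulated, 8.52 and 8.79 with HL7G and 8.63 to 8.78 with the agonists.

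For the interferon-stimulated genes the comparison with random lists was written down before it was run, and the other 2 tests were chosen after the result was seen. Level alone does not account for the whole difference, as the median lay at the percentile 100 among level-matched random lists. These lists match on level only, so they cannot exclude other effects of array or RNA quality. Ribosomal protein genes also lay high among such lists, at percentiles of 98.6 in mouse 1 and 97.6 in mouse 2. The mouse 1 unstimulated array alone does not account for the difference either, since the median was 1.98 without that array. A response to HL7G remains as a hypothesis, with a median of 1.18 in the mouse with the smaller difference. It may equally come from culture or handling common to all stimuli, and the IgG condition that would separate these was not analysed here.

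For the abundant transcripts both tests were chosen after the result was seen. Array or RNA quality could account for the difference in transcripts at 9 or more on the agonist arrays. The 2 unstimulated arrays, which also differ in animal, differed there by a median of 1.93, more than the 1.62 between HL7G and unstimulated (2.62 in mouse 1, 0.66 in mouse 2). At lower levels the unstimulated arrays differed by less than HL7G and unstimulated did. The medians were 0.78 against 2.13 at 8 to 9, 0.25 against 1.61 at 7 to 8 and 0.10 against 0.81 at 6 to 7. A change common to all 4 stimuli is also possible, but it was looked at in another set, the ribosomal protein genes, with stimulated medians of 7.69 to 8.49. Their lowest stimulated median exceeded the highest unstimulated one by 0.59, which restates the pattern that prompted the test. These explanations were not separated.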
